A study of Mus musculus and synthetic construct with 5 samples.

How the data were processed

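The data are read counts of sgRNAs from 2 pooled CRISPR-Cas9 knockout screens in immortalised mouse bone-marrow-derived macrophages with Cas9 and an NF-kB GFP reporter. Per the labels' protocols, cells were infected with a genome-scale sgRNA library at a multiplicity of infection given as 3 and an initial coverage of over 100 cells per sgRNA, selected with 10 ug/ml puromycin for 5 days starting 3 days after infection, and kept at over 1000 cells per sgRNA. Genomic DNA was amplified by nested PCR before sequencing, per the labels' protocols. The aligner or counter, its settings and the genome build were not given in the sources used here. The deposited counts are whole numbers of reads per sgRNA, neither normalized nor filtered in any way that the file headers state. The columns were tied to samples through the readme deposited with them and the sample titles, both viability days to the same sample of cells without LPS. The titles carry the prefixes WT and KRAB, whose meaning is not given, and no comparison uses them.

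The sorted table holds 236810 sgRNAs, the one for viability holds 265914, and 236794 are in both. Each sgRNA is 20 bases long. The sorted libraries had 4.43% (GFP low) and 7.04% (GFP high) of their sgRNAs at 0 reads, and the viability libraries 0.0218% (day 0) and 7.44% (day 21). Another table gives the viability counts in 4 bins per day, named by a base. Summed over bins they differed from the undivided counts by at most 25 reads for an sgRNA on day 0 and 33 on day 21. What the base marks is not given in the sources used here. The bins were treated as parts of 1 sample. The series description gives the last day as 20, and the columns and the readme give 21.

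The tables name targets by RefSeq transcript or microRNA ID, without coordinates. Of 21854 transcript IDs, 21610 (98.9%) were matched to a symbol through a RefSeq gene table of assembly GRCm38.p6, used for names only, and the rest kept their ID, as did 492 microRNA IDs. Transcripts of the same symbol were merged, which concerned 1669 symbols. The most common number of sgRNAs per transcript was 14 in the viability table and 13 in the sorted one. Negative controls were 5431 sgRNAs of random sequence in the viability table and 4966 in the sorted one. The sgRNAs against EGFP, mCherry, puroR and tetR were each treated as 1 target.

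Counts were scaled to equal library totals, 1 scaled read was added, and the log2 ratio of the 2 libraries was taken and centred on the median of the control sgRNAs. An sgRNA was used with at least 50 reads over both libraries and a gene with at least 4 such sgRNAs, which left 5227 controls and 19058 genes in the viability screen and 4301 controls and 18271 genes in the sorted cells. The score of a gene is the median over its sgRNAs. Its p is that of a two-sided permutation test of the mean rank of its sgRNAs among the controls against 100000 random sets of as many control sgRNAs, adjusted by the Benjamini-Hochberg method over all genes tested, and a gene was called at an adjusted p under 0.05. With 1 sample per group, a model across samples such as edgeR's quasi-likelihood test has no residual degrees of freedom, and the test used here measures the spread between sgRNAs within 2 libraries. No molecular identifiers were used here to tell PCR copies apart, and such copies are not independent molecules, so read depth overstates precision.

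The test was first run on simulated counts drawn at the real abundances with the scatter of the real controls and 200 genes changed. In the viability simulation it called 92.5% of genes lowered by 4 on the log2 scale, 65% of those lowered by 2, 12.5% of those lowered by 1, 55% of those raised by 2 and 2.5% of those raised by 1, with 26 calls among 18851 unchanged genes, of which 8.74% had a permutation p under 0.05. In the simulation of the sorted cells it called 86.5%, 15.4%, 5%, 15% and 2.5%, with 3 calls among 18057 unchanged genes.

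The 26 gene lists, the tests and the rule for naming genes were fixed before the data were examined. The rule takes the 10 highest and 10 lowest scores among called genes with at least 60% of sgRNAs on one side, every called member of the TLR4 and negative-regulator lists in the sorted cells, and from each other list up to 4 called members by smallest p, or the 2 with the largest score in size where none was called. Since no gene was called in the sorted cells, the 10 genes of smallest p and the genes called within the TLR4 list were named there after their values were seen. The median of each list was placed among those of 10000 random lists of as many genes matched on mean abundance in 10 classes. This abundance is the mean over the 2 libraries compared, so in the viability screen it includes the day 21 reads. The members of each list were also adjusted over the list alone.

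Alternatives were another centring, random sets from all gene-targeting sgRNAs, a minimum of 1 or 200 reads, a pseudocount of 10, the mean log2 ratio as the statistic, a Mann-Whitney test, leaving out the sgRNA farthest from the controls, odd- or even-numbered sgRNAs alone and, for lists, the mean. Added after seeing the data were 10000000 draws for genes with a permutation p of at most 0.001, the deposited ID as the unit and, for the viability screen, leaving out each bin and edgeR's quasi-likelihood model on the 8 bin columns with the bin as a block, followed by the set test fry of limma over the sgRNAs of a gene. The work used Python 3.11.15, NumPy 2.4.6, pandas 2.3.3, SciPy 1.17.1, matplotlib 3.10.9, R 4.3.3, edgeR 4.0.16 and limma 3.58.1.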

Results

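Pooled CRISPR-Cas9 knockout screens were read out in immortalised bone-marrow-derived macrophages of C57BL/6 mice that carried Cas9 and a green fluorescent protein (GFP) reporter of NF-kB, the transcription factor that drives much of the inflammatory response. Each cell received sgRNAs, the short RNAs that direct Cas9 to a gene, from a genome-wide library. An sgRNA that becomes rarer or more common among the cells can reflect what losing its gene does. Negative-control sgRNAs of random sequence also changed, with an SD of log2 ratios of 2.33 in the viability screen and 2.47 in the sorted cells. The labels describe 5 samples in 5 groups with 1 sample each. For one screen, cells were treated with 200 ng/ml lipopolysaccharide (LPS), the bacterial ligand of the receptor Tlr4, for 24 h and sorted, and the 20% of cells with the most and the 20% with the least GFP were sequenced. For the other, unsorted cells without LPS were sequenced on day 0 and on the last day, given as day 21 in the column names and as day 20 in the series description. The sorted libraries held 78760240 reads for low GFP and 76584288 for high GFP, over 236810 sgRNAs with a median of 189 and 157 reads each. The viability libraries held 107301434 reads on day 0 and 364166080 on day 21, over 265914 sgRNAs with a median of 306 and 702 reads. The plasmid library and the unsorted LPS cells were not analysed here. Because each group has 1 sample, no difference has a replicate check, and each test compares the sgRNAs of a gene with negative-control sgRNAs within 2 libraries, not the conditions.

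The viability comparison asks which genes the macrophages need to persist in culture. Of 19058 genes tested, 1259 fell and 38 rose from day 0 to day 21 relative to negative-control sgRNAs (adjusted p under 0.05, two-sided permutation test with Benjamini-Hochberg adjustment). In the viability simulation 8.74% of unchanged genes had a permutation p under 0.05 and 26 of 18851 were called, so the test was too lenient there. Of the real genes 16.3% had a permutation p under 0.05, and how many of the calls are false was not estimated. Scores below are the median log2 ratio of day 21 to day 0 over the sgRNAs of a gene, with the control median at 0, and the SD is over those sgRNAs. The 10 lowest scores included 5 ribosomal protein genes. Rpl19, a protein of the large ribosomal subunit, scored -8.08 ± 2.97 (SD, 11 sgRNAs, all 11 lower). Rpl36 scored -7.94 ± 0.85 over 6 sgRNAs, Rpl23a -7.92 ± 1.37 over 8, and Rps4x -7.85 ± 3.24 over 10. Rpl23 scored -7.78 ± 3.63 over 6. Arl2, a small GTPase that takes part in tubulin folding, had the lowest score of those named by the rule at -8.10 ± 0.95 over 4 sgRNAs. Rpa3, a subunit of the protein that coats single-stranded DNA, scored -7.89 ± 2.85, Lage3, of the complex that makes a universal tRNA modification, -7.80 ± 3.84, and Snrpd3, a core protein of the spliceosomal particles, -7.79 ± 4.18. Snrpd3 and Rpl23 were not called with at least 1 of the 4 bins left out. The microRNA gene mmu-mir-715 scored -7.88 ± 3.01, with 20 of its 21 sgRNAs lower, but how many sites these sgRNAs cut could not be counted without a genome, so the score cannot be assigned to loss of the microRNA. The adjusted permutation p of these genes lay between 0.000862 and 0.0427, the first being the smallest that 100000 draws could give here. The lowest scores are set by the pseudocount as well as by the loss, and with 10 scaled reads added in place of 1 the score of Rpl19 was -5.55.

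The genes that rose did so by far less. The sgRNAs of Adam10, a membrane protease that sheds cell-surface proteins, scored 2.99 ± 1.52 (SD, 12 sgRNAs, all 12 higher), or 7.94-fold above the controls, with an adjusted permutation p of 0.000862. Rasa3, an inactivator of Ras-like GTPases, scored 2.40 ± 3.33 with 12 of 14 sgRNAs higher. Ptpn6, the tyrosine phosphatase that opposes kinase signalling in blood cells, scored 2.04 ± 1.94 with 13 of 14 higher. Csk, the kinase that restrains the Src family, scored 1.53 ± 1.58 with 12 of 14 higher, and Gna13, a G protein subunit, 1.51 ± 1.06 with 12 of 14 higher. Bbc3, which encodes the pro-apoptotic protein PUMA, scored 1.43 ± 0.98 with all 9 sgRNAs higher. Ints6, a subunit of the Integrator complex, scored 1.52 ± 1.31, the transcription factor Klf16 1.61 ± 0.37, Zfp91 1.67 ± 3.62 and the olfactory receptor gene Olfr61 1.40 ± 1.03. Rasa3, Gna13, Bbc3, Zfp91 and Olfr61 were not called with at least 1 of the 4 bins left out, and of these all but Rasa3 were not called with the mean log2 ratio as the statistic. The deposited tables also split each viability library into 4 bins, which are parts of 1 sample and not replicates. Of the genes called, 1206 of the 1259 lower and 25 of the 38 higher lay on the same side in all 4 bins. The calls were made on the sum of these bins, so this count is not separate support for them.

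**Figure D1:**
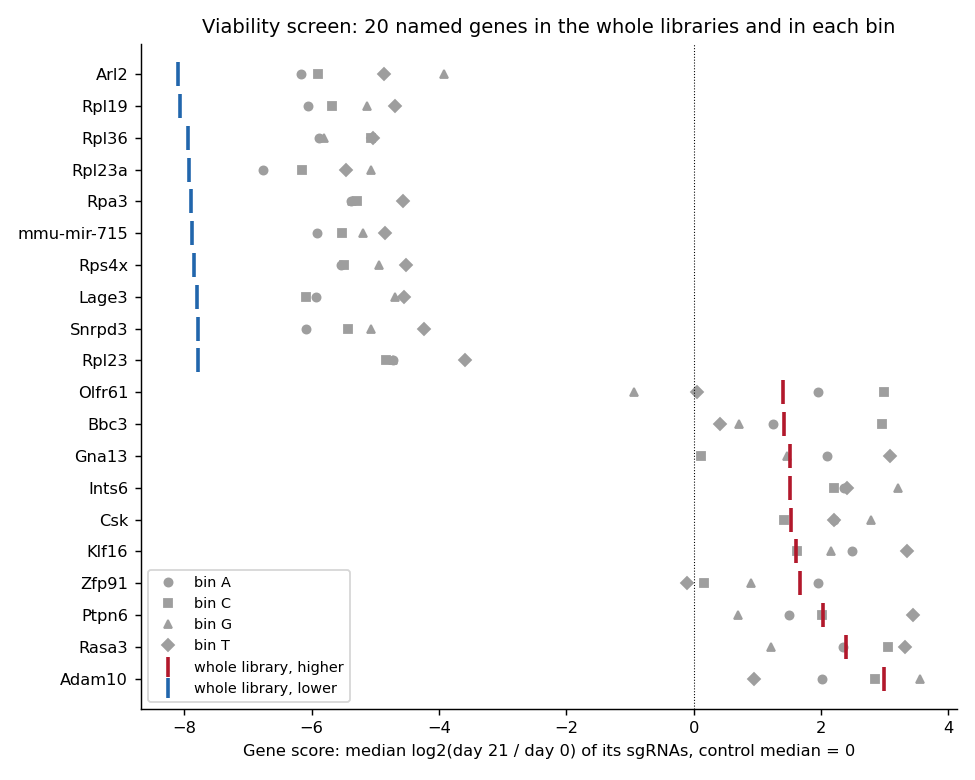
Gene scores in the viability screen for the 10 lowest and 10 highest named genes, as the median log2 ratio of day 21 to day 0 over the sgRNAs of each gene with the control median at 0. Coloured bars, from -8.10 for Arl2 to 2.99 for Adam10, stand for the whole libraries and grey symbols for each of 4 bins, which lie on both sides of 0 for Olfr61 and Zfp91.

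Groups of housekeeping genes fixed in advance had many members that fell. Of 69 genes of the cytosolic ribosome tested, 53 fell and none rose, 60 fell when adjusted over the list alone, and the list median of -5.52 lay below that of all 10000 random lists matched on abundance. Of 34 DNA replication genes, 22 fell (28 adjusted over the list alone), with a list median of -2.47, among them Prim1 at -6.94 ± 3.19, the clamp protein Pcna at -6.78 ± 3.46 and Pold3 at -6.77 ± 3.37. Of 35 proteasome genes, 22 fell (26 adjusted over the list alone), with a list median of -2.08, Psma3 at -7.21 ± 2.80 and Psmb3 at -7.14 ± 2.94. In the CCT chaperonin, which folds actin and tubulin, 6 of 8 genes fell and all 8 when adjusted over the list alone, led by Cct4 at -7.60 ± 3.76, with a list median of -4.06. Among core spliceosome genes 13 of 28 fell (20 adjusted over the list alone), with a list median of -2.23, Snrnp200 at -7.08 ± 3.19 and Sf3b2 at -6.84 ± 2.95. Among aminoacyl-tRNA synthetases 13 of 20 fell (16 adjusted over the list alone), with a list median of -1.82, Farsa at -6.42 ± 2.85 and Qars at -5.96 ± 3.07. Of 10 RNA polymerase II subunits, 3 fell (7 adjusted over the list alone), with a list median of -1.92, namely Polr2h at -6.06 ± 3.09, Polr2g at -4.94 ± 3.97 and Polr2b at -2.34 ± 3.48. Polr2g and Polr2b were not called against random sets of gene-targeting sgRNAs. The calls were also lost, for Polr2g with at least 200 reads per sgRNA (-1.53) and for Polr2b with bin T left out. Of 36 genes of Mediator and P-TEFb, which help RNA polymerase II to start and to elongate, 6 fell (10 adjusted over the list alone), including Cdk9 at -6.45 ± 3.88 and Med12 at -5.35 ± 3.13, while 30 were not called and the list median of -0.40 lay at percentile 16.4, inside the central 95% of random lists. With at least 200 reads per sgRNA the score of Cdk9 was -1.01, that of Farsa -2.52, that of Pold3 -3.04 and that of Sf3b2 -3.47, all still called.

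Part of the genes in 4 lists of mitochondrial, glycosylation and V-ATPase genes also fell. Of 74 mitochondrial ribosome genes, 23 fell (32 adjusted over the list alone), with Mrpl20 at -6.53 ± 1.77 and Mrpl51 at -5.72 ± 2.96. Of 34 genes of respiratory complex I, 7 fell (13 adjusted over the list alone), by less, with Ndufb4 at -2.88 ± 3.51 and Ndufs1 at -1.70 ± 2.27, both of which were not called with at least 1 bin left out or against random sets of gene-targeting sgRNAs. Of 24 genes of N-glycosylation, 12 fell (19 adjusted over the list alone), with Alg2 at -7.27 ± 3.64 and Rpn1 at -7.19 ± 3.84. Of 24 subunits of the V-ATPase, the pump that acidifies lysosomes, 6 fell in both counts, with Atp6v1d at -6.57 ± 2.92 and Atp6v1a at -2.77 ± 3.45. With at least 200 reads per sgRNA Atp6v1d scored -4.18 and Atp6v1a -2.05, both still called. The medians of these 4 lists, -1.70, -1.35, -2.15 and -1.13, lay below those of all 10000 random lists, except for the V-ATPase at percentile 0.04. With at least 200 reads per sgRNA the V-ATPase median was -0.45, that of the mitochondrial ribosome -1.21 and that of the CCT chaperonin -2.27.

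**Figure D2:**
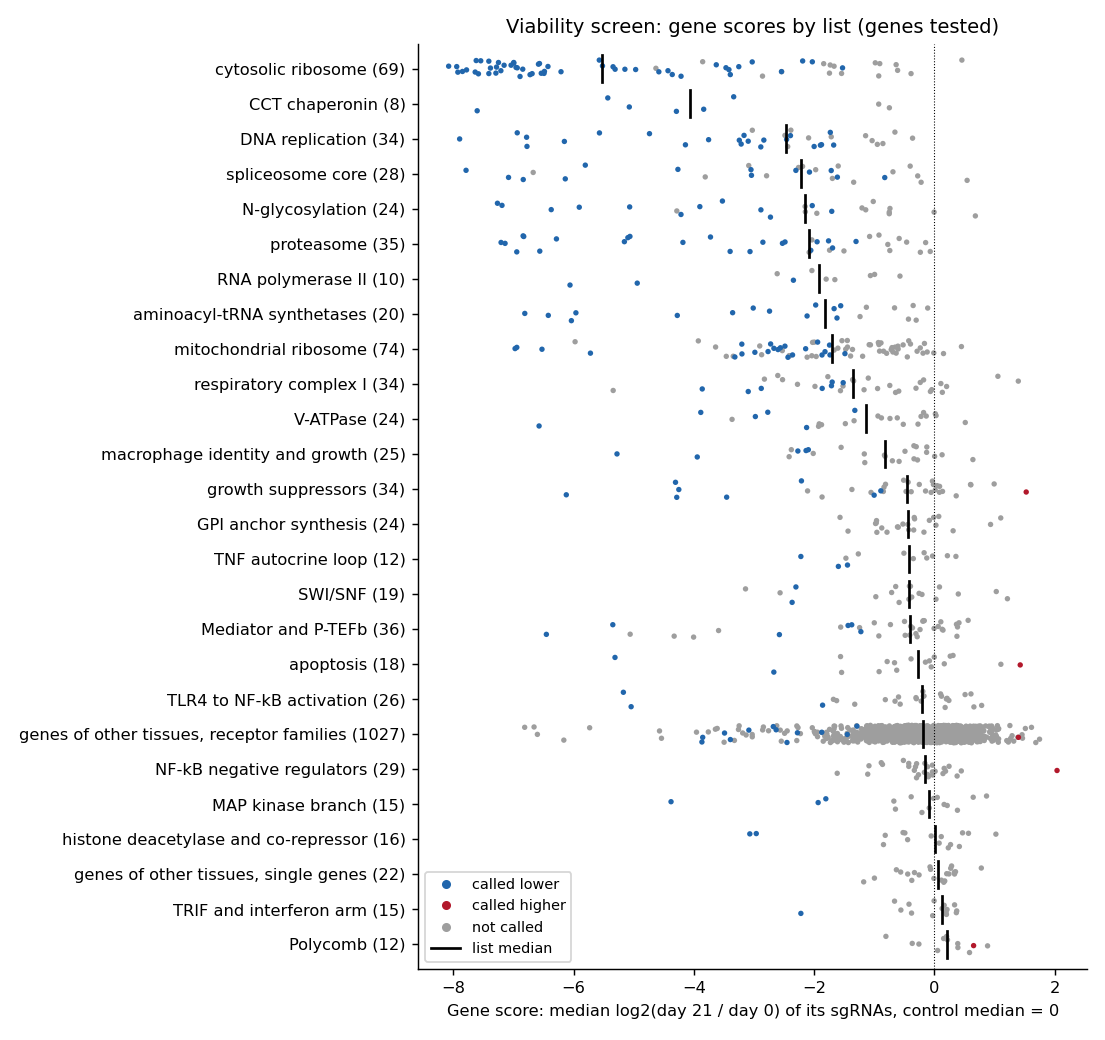
Scores of all tested genes of the 26 lists in the viability screen, as log2 ratios with the control median at 0. Each point is a gene, blue where called lower, red where called higher and grey where not called, and black bars are list medians, from 0.21 for Polycomb genes to -5.52 for the cytosolic ribosome.

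Genes of macrophage identity and growth had a list median of -0.82, below all but 0.01% of random lists, and 5 of 25 fell (9 adjusted over the list alone). Spi1, which encodes a transcription factor that specifies myeloid cells, scored -5.28 ± 4.06 with 11 of 14 sgRNAs lower and an adjusted permutation p of 0.0293. Fli1, a transcription factor of the same family, scored -2.10 ± 3.00 with all 14 sgRNAs lower, and Irf8, another regulator of macrophage development, -2.13 ± 2.65. The kinase Syk scored -2.27 ± 2.82 and the phospholipase Plcg2 -3.94 ± 3.50, both of which signal downstream of immune receptors. Csf1r, the receptor for the macrophage growth factor Csf1, was not called at -0.70 ± 2.72 over 14 sgRNAs. Spi1 and Csf1r were singled out after their values were seen, and whether Spi1 stays called under the alternatives was not recorded. Syk and Irf8 were not called with at least 1 of the 4 bins left out or against random sets of gene-targeting sgRNAs.

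Several genes of inflammatory signalling fell without LPS, although the list medians, -0.21 for TLR4 to NF-kB activation, -0.43 for the TNF autocrine loop, 0.13 for the TRIF and interferon arm, -0.09 for the MAP kinase branch and -0.16 for negative regulators, lay inside the central 95% of random lists. In the same order 11.5%, 25%, 6.67%, 20% and 0% of their genes fell. Of all genes tested 6.81% were called, lower or higher, and these lists are small. Centring on all sgRNAs turns the TLR4, MAP kinase and negative-regulator medians to 0.07, 0.19 and 0.11, and the mean for the TRIF arm was -0.16. From the list of TLR4 to NF-kB activation 3 of 26 fell (4 adjusted over the list alone). These were the receptor chaperone Hsp90b1 at -5.17 ± 3.31, the kinase Map3k7 at -5.04 ± 2.85 with all 14 sgRNAs lower, and Ikbkg at -1.86 ± 3.09. Ikbkg is the regulatory subunit of the IkB kinase. With at least 200 reads per sgRNA Hsp90b1 scored -2.38, Map3k7 -3.22 and Ikbkg -1.90. Of 12 genes of the TNF autocrine loop, 3 fell (4 adjusted over the list alone), namely Ripk1 at -2.22 ± 3.13, Traf2 at -1.60 ± 3.43 and the TNF-releasing protease Adam17 at -1.45 ± 2.68. Ripk1 was also the only 1 of 15 genes of the TRIF and interferon arm to fall. In the MAP kinase branch 3 of 15 genes fell, the same over the list alone, including Map2k1 at -4.38 ± 3.45 and Map2k2 at -1.81 ± 1.33. With at least 200 reads per sgRNA Map2k1 scored -2.345 and Map2k2 -1.94. None of 29 negative regulators of NF-kB fell, and Ptpn6 alone rose, in both counts. Adam17, Traf2, Ikbkg, Map2k1 and Map2k2 were not called with at least 1 of the 4 bins left out. Of these, all but Map2k1 were also not called against random sets of gene-targeting sgRNAs, and Traf2 also not with at least 200 reads per sgRNA (-0.40).

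Of 34 growth suppressors, 8 fell and 1 rose, the same when adjusted over the list alone, with a list median of -0.45. Those that fell included Keap1 at -6.12 ± 4.11 and Cul3 at -4.25 ± 3.09, which together mark the transcription factor Nrf2 for degradation. The kinase Stk11 at -4.31 ± 3.51, the deubiquitinase Bap1 at -3.45 ± 3.32 and Tsc2, an inhibitor of mTOR signalling, at -2.21 ± 3.76 also fell, while Csk rose. With at least 200 reads per sgRNA Stk11 scored -4.03, Bap1 -1.81 and Tsc2 -1.38, all still called. Trp53 was not called, at -0.81 ± 2.74, and was singled out with Keap1 and Cul3 after the values were seen. Whether Keap1 and Cul3 stay called under the alternatives was not recorded. Of 18 apoptosis genes, the survival factor Mcl1 at -5.31 ± 3.47 and Casp8 at -2.67 ± 3.57 fell and Bbc3 rose (4 and 2 adjusted over the list alone), with a list median of -0.27 that all-sgRNA centring turns to 0.0042. In the SWI/SNF remodelling complex Smarcb1 at -2.30 ± 3.44 and Smarce1 at -2.37 ± 3.40 fell among 19 genes (3 lower and 1 higher adjusted over the list alone), with a list median of -0.42. The call of Smarce1 was lost with at least 200 reads per sgRNA (-0.91) and against random sets of gene-targeting sgRNAs. Among 16 histone deacetylase and co-repressor genes Hdac3 at -3.07 ± 3.42 and Chd4 at -2.96 ± 3.32 fell in both counts, with a list median of 0.01 and a mean of -0.38. Hdac3 and Casp8 were not called against random sets of gene-targeting sgRNAs. The Polycomb gene Kdm2b rose to 0.65 ± 1.90 among 12 genes, with an adjusted permutation p of 0.0468, the list median being 0.21, but it was called under only 6 of 17 alternatives, and its score was -0.0095 with even-numbered sgRNAs alone. None of 24 genes of GPI anchor synthesis was called, Pigu at -1.57 ± 3.16 and Pign at -1.44 ± 2.79 having the largest scores in size and the list median being -0.44.

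Among 1027 olfactory and other receptor genes, 12 fell and 1 rose (none adjusted over the list alone). Their list median of -0.19 (0.08 with all-sgRNA centring) lay above those of all 10000 matched random lists, whose median was -0.43. The median score of all genes tested was -0.25. The matching uses reads of both days and so depends on the outcome itself, and this position cannot show that receptor genes persisted more than others. Among 22 single genes of other tissues none was called, with a list median of 0.05 and a mean of -0.08. Of the targets that are not mouse genes, the puromycin resistance gene puroR fell, at -3.87 ± 2.46 with 9 of 10 sgRNAs lower and an adjusted permutation p of 0.011, a call lost with bin G left out and against random sets of gene-targeting sgRNAs. EGFP at -0.39 ± 2.60, mCherry at -0.94 ± 3.21 and tetR at -0.33 ± 1.62 were not called.

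The count of calls depends on the reference. The median of all gene-targeting sgRNAs lay at -0.28 against the controls and their SD was 2.66 against 2.33, and the effects of median and spread on the count were not separated. Drawn from all gene-targeting sgRNAs in place of controls, random sets left 580 genes lower and 73 higher, and centring on all sgRNAs raises every score by 0.27.

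The sorted comparison asks which genes LPS-treated macrophages need to switch the NF-kB reporter on or to hold it down. Scores are now log2 ratios of GFP high to GFP low, so a negative score means that sgRNAs of the gene were more common among cells with little GFP. The sgRNAs against EGFP, the reporter's own coding sequence, scored -3.06 ± 2.61 (SD, 12 sgRNAs, all 12 lower). Myd88, the adaptor through which TLR4 signals to NF-kB, scored -3.71 ± 2.73 with 11 of 12 sgRNAs lower, and Tirap, which brings Myd88 to the receptor, -5.17 ± 2.26 with all 7 lower. None of these passed the adjustment over all 18271 genes tested. EGFP and Myd88 had the lowest adjusted permutation p, 0.0914, from a permutation p of 1e-05, the smallest that 100000 draws can give, and Tirap had 0.305. With no gene called higher or lower by the permutation test, 1151 genes (6.30%) had an unadjusted permutation p under 0.05, against 5.74% of unchanged genes in simulated sorted counts, and the Mann-Whitney test also called 0.

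Among the 26 genes of TLR4 to NF-kB activation, a list fixed before the data were examined, 7 were lower and 1 was higher in GFP-high cells when adjusted over the list alone, and the list median of -0.68 lay below that of all 10000 random lists. Besides Myd88 and Tirap, with permutation p values adjusted over the list alone of 0.00026 and 0.00078, the lower genes were Tlr4, Ly96, Cnpy3, Irak4 and Rela. The receptor Tlr4 scored -1.69 ± 2.23 with 10 of 11 sgRNAs lower, and its LPS-binding partner Ly96 -2.81 ± 2.32 with all 8 lower. Cnpy3, a chaperone of Toll-like receptors, scored -2.87 ± 2.42 with 9 of 10 lower. The kinase Irak4 scored -1.39 ± 1.76 with 11 of 13 lower, and Rela, the NF-kB subunit that activates transcription, -1.34 ± 2.21 with 12 of 14 lower. Tab2, an adaptor of the kinase Map3k7, was the gene that was higher, at 1.95 ± 2.75 with 6 of 7 sgRNAs higher, and it was not called without its farthest sgRNA. Within the list, Rela was not called against random sets of gene-targeting sgRNAs, Irak4 and Rela not with the mean log2 ratio as the statistic, and Ly96 not with at least 200 reads per sgRNA. With odd-numbered sgRNAs alone only Cnpy3 was lower, and with even-numbered sgRNAs alone only Ly96 and Myd88, so Tlr4, Tirap, Irak4 and Rela were called with neither set, Tirap having too few even-numbered sgRNAs to test. The co-receptor Cd14 at -0.91, Irak1 at -1.05, Traf6 at -0.12 and Ikbkb at -0.36, singled out after their values were seen, did not pass even within the list.

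**Figure D3:**
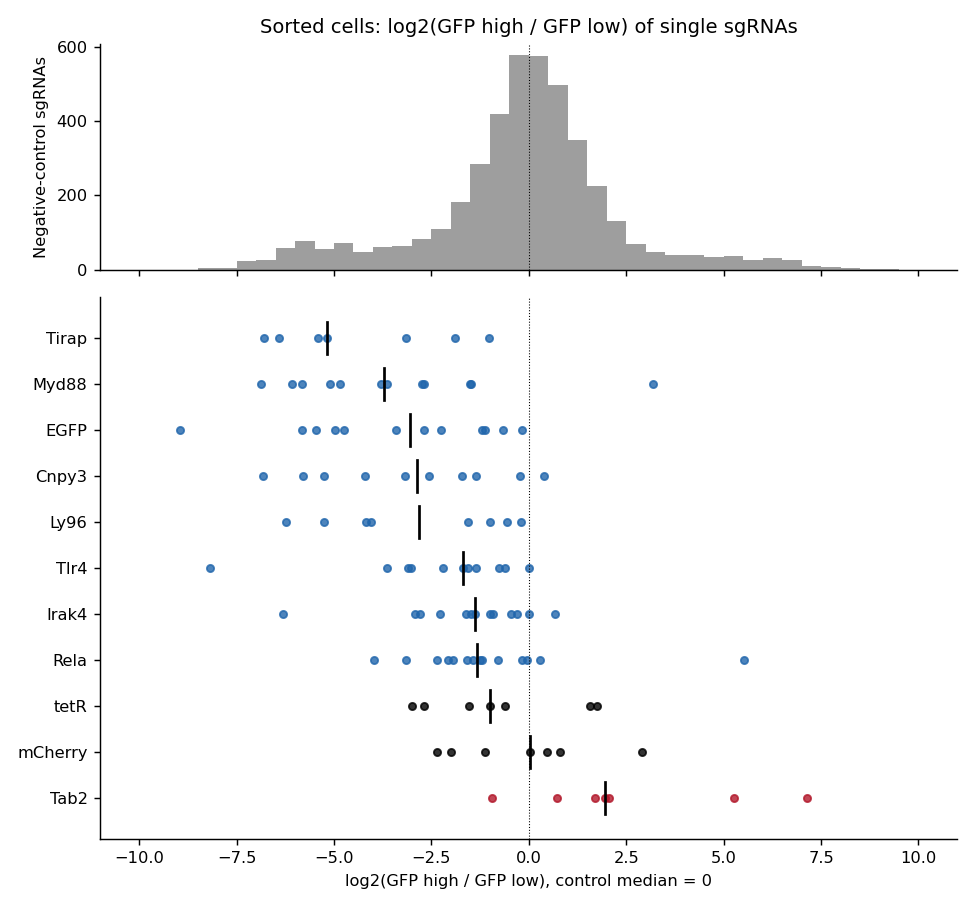
Log2 ratios of GFP high to GFP low in the sorted cells, with the control median at 0. The upper panel counts negative-control sgRNAs, and in the lower panel each point is 1 sgRNA of the gene named (blue or red for medians below or above 0, black for vector controls, bars for medians), all 12 of EGFP and all 7 of Tirap lying below 0.

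Negative regulators of NF-kB showed no shift as a group. None of 28 was called over all genes or over the list alone, the list median was 0.02, and Tnfaip3 at 0.29, Nfkbia at 0.07 and Cyld at 0.58, all singled out after their values were seen, lay close to the controls. Genes of GPI anchor synthesis, the pathway that attaches proteins such as Cd14 to the membrane, had a list median of -0.52, below all but 0.09% of random lists, with 19 of 24 genes below 0 and no single gene called over the list alone. Pigu scored -2.18 ± 3.85 and Pigg -2.12 ± 3.11. The SWI/SNF median of -0.39 lay at percentile 2.12 and that of the aminoacyl-tRNA synthetases, -0.58, at percentile 2.17. The spliceosome median of 0.39 lay at percentile 99.3 and the CCT chaperonin median of 0.68 at percentile 97.8. Over the alternatives, the list mean included, these ranged from -0.64 to -0.14 for SWI/SNF, from -1.21 to -0.14 for the aminoacyl-tRNA synthetases, from 0.05 to 0.55 for the spliceosome and from -0.27 to 1.25 for the CCT chaperonin.

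The other signalling lists had medians inside the central 95% of random lists. These were the TNF autocrine loop at -0.28, the MAP kinase branch at 0.11 and the TRIF and interferon arm at 0.07, none of firm sign. The TNF median was 0.27 with at least 200 reads per sgRNA, the MAP kinase median -0.19 with odd-numbered sgRNAs and the TRIF median -0.02 with even-numbered sgRNAs. Among their members, Birc2 at -2.61 ± 2.89, Mapk8 at -1.72 ± 2.42 and Ifnb1 at -2.93 ± 3.84 were not called. Macrophage identity and growth had a median of 0.17, which turned to -0.35 with even-numbered sgRNAs alone. In that list Csf2ra, a subunit of the receptor for the growth factor GM-CSF, was higher when adjusted over the list alone, at 2.47 ± 1.99 with 9 of 10 sgRNAs higher. In the same way Snrpa1 at 2.88 ± 1.90, Pcgf6 at 2.18 ± 2.10, Cct3 at 1.92 ± 2.06 and Gars at 1.64 ± 1.92 were higher within the spliceosome, Polycomb, CCT chaperonin and aminoacyl-tRNA synthetase lists. Their sgRNAs with enough reads numbered 5, 9, 7 and 10. Psmd3 at -6.20 ± 3.51 and Psma7 at -2.29, named after its value was seen, were lower within the proteasome list. Psmd3 had 7 sgRNAs with enough reads here, against 15 in the viability screen, where it fell to -6.56. Controls were not matched to genes on reads, and the tenth of controls with the fewest reads had an SD of 4.10. Outside the lists, Acsm4 at -4.12 ± 2.54, Gpr173 at -2.34 ± 2.21, Ghdc at 1.81 ± 1.07, Plac8 at 2.87 ± 2.30 and Lipe at 1.33 ± 1.34 were among the 10 genes of smallest permutation p, chosen after their values were seen, and were not called. The vector controls mCherry at 0.04 ± 1.82 and tetR at -0.997 ± 1.88 were not called. The puroR target could not be tested here, since fewer than 4 of its 10 sgRNAs in the sorted table had at least 50 reads.

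The medians of the lists not yet given for the sorted cells were 0.02 for the cytosolic ribosome, -0.02 for the proteasome, 0.38 for RNA polymerase II, 0.17 for DNA replication, 0.03 for Mediator and P-TEFb, 0.06 for histone deacetylases and co-repressors, 0.20 for Polycomb, -0.24 for the V-ATPase, 0.03 for the mitochondrial ribosome, 0.07 for respiratory complex I, -0.18 for N-glycosylation, 0.12 for growth suppressors, 0.05 for apoptosis, 0.01 for the receptor families and 0.28 for single genes of other tissues. All of these lay inside the central 95% of random lists. The Polycomb value ranged from 0.14 to 0.68 over the alternatives, the list mean included. The signs of the others are not firm, as each changed under at least 1 alternative. Over all 26 lists, 12 have a mean of the opposite sign, among them RNA polymerase II with a mean of -0.28 and the V-ATPase with a mean of 0.06.

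**Figure D4:**
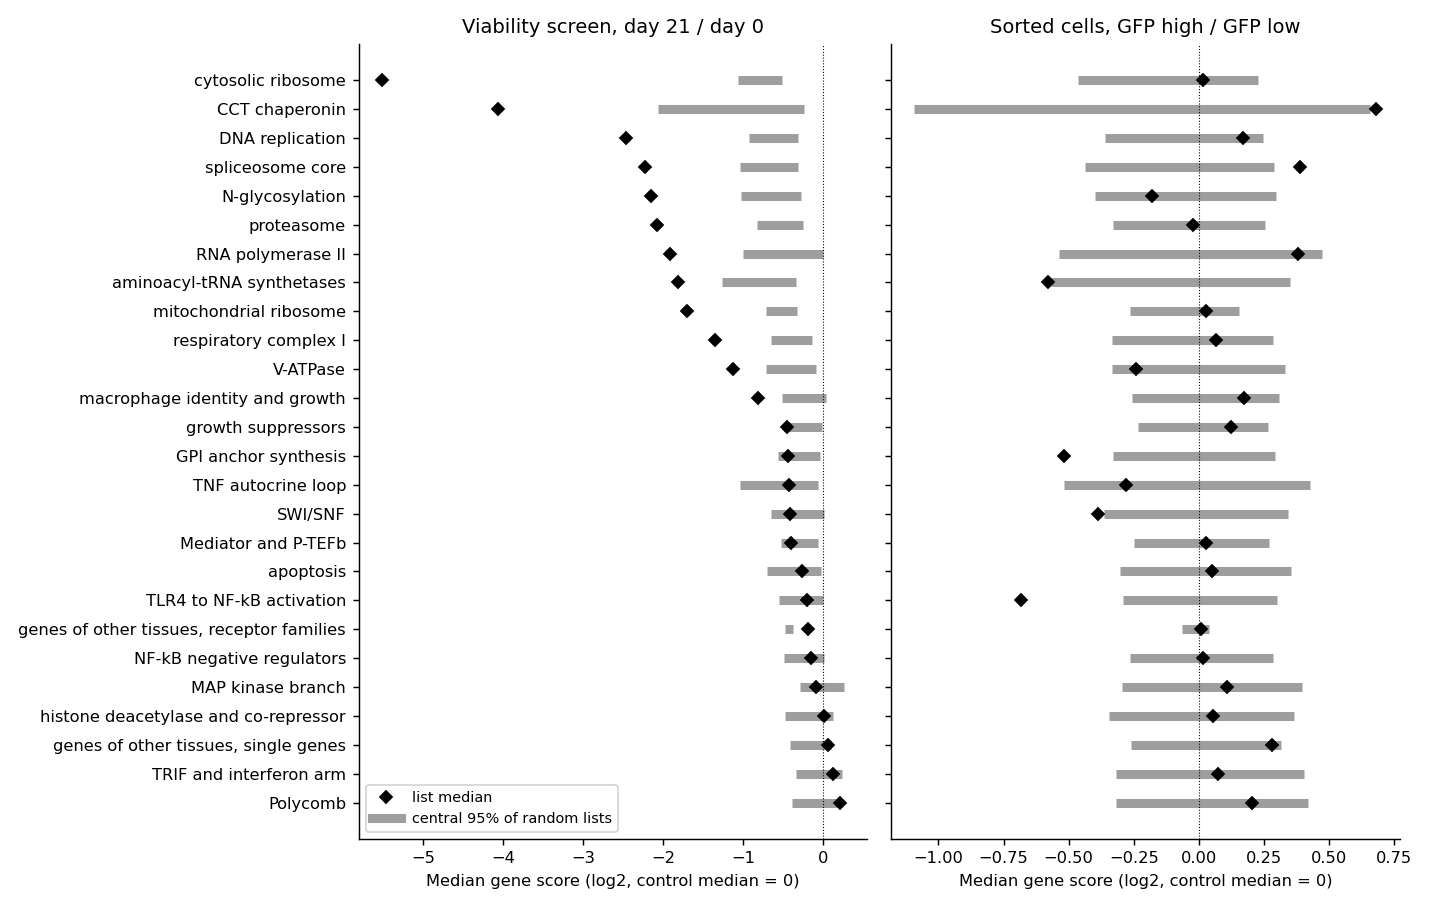
List medians (diamonds) and the central 95% of the medians of 10000 abundance-matched random lists (grey bars), as log2 scores in the viability screen on the left and in the sorted cells on the right, on different scales. In the sorted cells TLR4 to NF-kB activation lies below its bar, at -0.68, as do GPI anchor synthesis, SWI/SNF and the aminoacyl-tRNA synthetases. The spliceosome, at 0.39, and the CCT chaperonin, at 0.68, lie above theirs. In the viability screen TLR4 to NF-kB activation lies inside its bar, at -0.21 (0.07 with all-sgRNA centring).

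Control sgRNAs in the sorted cells scattered with an SD of 2.47, from 4.10 in the tenth of controls with the fewest reads to 0.82 in the tenth with the most, and only 34 of the 74 ribosomal genes in the sorted table had enough reads to test. On simulated sorted counts the test called 86.5% of genes lowered by 4 on the log2 scale and 15.4% of those lowered by 2, so differences of the size seen for Tlr4 were mostly not detectable over all genes with this scatter between sgRNAs. Across the 18270 genes tested in both screens, the scores of the 2 screens had a Spearman correlation of 0.01 and a Pearson correlation of 0.05, over genes, which are not independent replicates.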

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

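No paired analysis was possible because each group has 1 sample, and both viability libraries were tied to the same sample, the cells without LPS. Comparisons with the plasmid library or the unsorted LPS cells, a block on the WT and KRAB prefixes and leaving out replicates were planned and not run, since these libraries were not analysed here and no column carries the prefixes. The alternatives with 10000000 draws, with deposited IDs and on the bins were chosen after seeing the data. Centring on all sgRNAs shifts genes and controls alike, so it leaves every rank test as it was. In the viability screen the 1297 calls (38 higher, 1259 lower) became 653 (73 higher, 580 lower) with random sets from all gene-targeting sgRNAs, of which 618 were among the 1297. They became 441 (18 higher, 423 lower) with odd-numbered and 357 (14 higher, 343 lower) with even-numbered sgRNAs, where each gene has fewer sgRNAs. Without the farthest sgRNA 62 were higher and 815 lower, and with the mean log2 ratio as the statistic 6 were higher, the total of 1659 lying within 1.5 times the count given. Under edgeR on the bins with fry 5816 genes were called (14 higher, 5802 lower), and 361 of 5227 control sgRNAs were themselves called by that model. Leaving out a bin gave 1022 to 1134 calls. Of the 89 named genes called in the viability screen, 17 stayed called under every alternative that could test them and 52 under all but the odd- and even-numbered sets. Among the 20 genes of highest and lowest score, Snrpd3, Rpl23, Olfr61, Zfp91, Bbc3, Gna13, Klf16, Csk, Ptpn6 and Rasa3 lost the call under at least 1 alternative other than the odd- and even-numbered sets, Csk and Ptpn6 only under edgeR on the bins with fry, and the cause was not tested. With at least 1 bin left out 29 of the 89 lost the call, among them puroR, Syk, Irf8, Casp8, Ikbkg, Ndufb4, Ndufs1, Polr2b, Rasa3, Gna13 and Bbc3. Against random sets of gene-targeting sgRNAs 25 of the 89 lost the call. With at least 200 reads 23 of 86 such scores were over 1.5 times nearer to 0 and 12 lost the call. Kdm2b turned to -0.0095 with even-numbered sgRNAs. In the sorted cells no alternative called a gene over all genes tested, the lowest adjusted p being 0.0914 to 0.523 across alternatives, and 0.124 with 10000000 draws, so the number of draws was not what kept EGFP and Myd88 from the threshold. Within the TLR4 list 5 to 9 genes were lower under the other alternatives, against 1 with odd-numbered and 2 with even-numbered sgRNAs. The higher gene, Tab2, was lost without the farthest sgRNA (0) and with even-numbered sgRNAs (0). The median of the TLR4 list ranged from -0.47 to -0.96 and that of GPI anchor synthesis from -0.47 to -0.99 over all alternatives, the list mean included. With the mean in place of the median, 3 list values in the viability screen and 12 in the sorted cells changed sign. With all-sgRNA centring the viability medians of TLR4 activation, NF-kB negative regulators, the MAP kinase branch, apoptosis and the receptor families turned from below to above 0. With at least 200 reads the viability medians of all 11 housekeeping lists outside the central 95% moved towards 0. In the sorted cells the control SD was 4.10 at a median of 40.9 scaled reads per sgRNA and 0.82 at 1257. Over all controls, Poisson draws at the observed counts gave an SD of 0.159 against 2.47. These values argue against counting error as the main source of the scatter, and deeper sequencing itself was not tested.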

Other observations

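The library also targets microRNA genes, which no list covered. In the viability screen 14 of 373 microRNA genes tested fell and none rose, or 3.75% against 6.81% of all genes tested, and their median score of -0.25 equalled that of all genes to 2 decimals. Besides mmu-mir-715, the lowest were mmu-mir-191 at -7.00 with all 5 sgRNAs lower, mmu-mir-689-2 at -6.75 with all 11 lower, mmu-mir-682 at -5.18 with 11 of 13 lower, and mmu-mir-1186 at -4.33 with 12 of 14 lower. The score of mmu-mir-191 was above 0 in 1 of the 4 bins. In the sorted cells none of 321 microRNA genes was called. These genes were singled out after their values were seen. How many sites their sgRNAs cut could not be counted without a genome, so the low scores cannot be assigned to loss of the microRNAs.

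Of the tests below, those of GC content, of a fixed effect of each sgRNA, of the share of reads per bin and of puroR were chosen after the result was seen. The design has no group that separates a biological explanation for any of these patterns, so none was tested.

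In the viability screen sgRNAs against genes lay below the negative controls, with a median of -0.28. GC content is argued against as the main source, since the difference was -0.28 with each GC class weighted as in the controls, and so is the number of reads on day 0, with -0.23 after the same weighting over classes of day 0 reads. The sgRNAs against 223 genes of families used in other tissues had a median of -0.15 (95% bootstrap interval -0.24 to -0.06), so a cost of cutting DNA whichever gene is hit may account for part of the shift. The families were named before the test, but macrophages might still use some of them, and the random-sequence controls have no known target to cut.

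Control sgRNAs scattered widely in both screens, with an SD of 2.47 in the sorted cells. Read sampling is excluded as the whole cause in either screen, because Poisson draws at the observed counts, which cover counting error only, gave an SD of 0.159 in the sorted cells and 0.122 against 2.33 in the viability screen. A fixed effect of each sgRNA on growth or amplification stays open: the highest correlation between the ratios of control sgRNAs in 2 bins of the viability screen was 0.198, but all sgRNAs, including those of genes the cells need, reached only 0.262, and the sorted libraries have no bins. The median share of a control sgRNA's reads in its fullest bin rose by 28.4 percentage points, from 39.6% on day 0 to 68.0% on day 21, where reads placed at random would give 31.2%, and 25.6% of controls had over 90% of their reads in 1 bin on day 21 against 0.408% on day 0. Few cell lineages behind each sgRNA by the last day could give this, a hypothesis that assumes the bins hold different cells. Set beside it, the labels state an initial coverage of over 100 cells per sgRNA and over 1000 kept in culture, and lineages were not counted. In the sorted cells 1.13% of controls had at least 200 reads in one library and at most 2 in the other, which few sorted cells per sgRNA could give, but the labels state no number of sorted cells, so this cannot be told apart from losses in PCR.

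The puroR sgRNAs fell to -3.87 in the viability screen, a call lost with bin G left out, although the labels place puromycin only in the days after infection. Cutting inside the delivered vector could do this to mCherry sgRNAs as well, whose median was -0.94, and a two-sided permutation test of puroR against mCherry gave p = 0.276, so with 10 and 11 sgRNAs this stays open. GC content stays open too. None of 10000 sets of control sgRNAs of matched GC class (0%) reached so low a median, but the puroR sgRNAs have a median GC content of 80%, which only 7 control sgRNAs reach, so the match is poor where it matters. A loss of resistance while puromycin was present after day 0 was not tested, since the sources do not place day 0 relative to the selection.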
